A study of Mus musculus with 4 samples.

How the data were processed

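Libraries were prepared from C2C12 cells by poly(A) selection and a library kit for Illumina sequencing, per the labels' protocols. The deposited table holds raw read counts per gene for the 4 libraries, as whole numbers that were not normalized, with gene identifiers, names and biotypes. Per the submitters' processing notes, the tools used were FastQC, MultiQC, fastp, Picard, featureCounts and edgeR and the genome build was GRCm38. The aligner, the strand setting, the annotation release and the treatment of reads that map to several places are not given in the sources used here. The table has 52636 gene rows, of which 17976 had no count in any library and 0 had no name. No column belonged to other samples.

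The counts carried 2 signs of how reads were assigned. Among values from 1 to 12, 75.8% to 79.6% were even in each library. The predicted gene Gm20388, which spans chromosome 8 from 119910841 to 124345722 (GRCm38), held 397524 counts over the 4 libraries, against 407731 summed over the 207 genes inside it. Reads were therefore treated as possibly shared between genes that overlap on either strand, although not every such pair showed it (mt-Nd4l, which overlaps mt-Nd4, had 9, 26, 5 and 7 counts in the 4 libraries). Gene positions were taken from GENCODE release M21 (GRCm38), to which 52489 of 52636 identifiers matched. A gene was marked as sharing reads when an overlapping gene had a count of 20% or more of its own. A gene that spans it entirely, such as Gm20388, counted for this only with what its count exceeded the sum of the genes inside it. The mark compares total counts and does not show that any read was shared (mt-Nd4l carries it). Where a gene is said below to share reads or to have shared reads, this mark is meant.

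Genes were kept by filterByExpr (minimum count 10, minimum total 15), leaving 18998 genes. Libraries were scaled by TMM and the groups compared with edgeR 4.0.16 (R 4.3.3), by glmQLFit and glmQLFTest on all 4 libraries without further covariates, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. This test is meant by edgeR adjusted p in the text. Standard errors of log2 fold changes are the estimate divided by the square root of the F statistic. CPM values use TMM effective library sizes and are given as mean ± SD over 2 libraries. Total counts ran from 10283135 to 24362899 per library, and 3 counts, the upper limit that a count of 0 allows, correspond to 0.298, 0.219, 0.201 and 0.112 CPM in control replicates 1 and 2 and sesaminol replicates 1 and 2. If both reads of a pair were counted singly, these limits are too low. No libraries were duplicates: a chi-square test of counts per degree of freedom gave 6.96 for the controls, 44.8 for the sesaminol pair and 46.9 to 80.8 between groups.

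The design, 28 gene lists and the rule for naming genes were fixed before the data were examined. The named genes are the 10 largest rises and 10 largest falls among called genes with a mean of at least 5 CPM, no overlap between groups and a symbol that is not a predicted gene, up to 4 members of each list with the smallest adjusted p, and a set of 20 anchor genes. A gene outside this rule is said to have been named after its values were seen. The lists were set from textbook knowledge and not on these samples. Lists were tested with camera (limma 3.58.1, preset inter-gene correlation 0.01, Benjamini-Hochberg over the 28 lists), and again with an estimated correlation and with fry. Of the 28 lists, 16 passed with the preset correlation and 0 with the estimated one (6 at an unadjusted p under 0.05), while fry passed 7 in its directional test and 20 in its mixed test. The 4 muscle lists were also tested as a single list. The alternatives were other scalings, filters and thresholds, DESeq2 1.42.0, limma-voom, the replicate number as a block, and leaving out each library. Thinned or halved counts, corrections for GC content and gene length (the genomic span, introns included), and leaving out genes with shared reads were added after the data were seen. Libraries left alone in a group by this are assumed to vary like the other group.

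The procedure was tested on simulated data, with counts for 18335 genes at the means and depths of these libraries. For the comparison of sesaminol with control, edgeR recovered 32% of 100 genes changed 2-fold and 73% of 100 genes changed 4-fold, with 6 false calls. In a second simulation camera found the sarcomere list, shifted 2-fold, and 0 of the others. The simulated genes were drawn independently, so this could not test how camera fares when genes of a list vary together. In the data the estimated correlation reached 0.903, for cholesterol synthesis. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.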

Results

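Polyadenylated RNA was sequenced from C2C12, a mouse myoblast line that can fuse into contractile myotubes. The cells had been kept in adipogenic medium for up to 8 days, and 1 group also received 50 µM sesaminol, a lignan of sesame seed. There were 2 control and 2 sesaminol libraries. Total counts were 10283135 and 14083165 in control replicates 1 and 2, and 15807638 and 24362899 in sesaminol replicates 1 and 2. Nothing states that the libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Across genes, log2 CPM correlated at a Pearson r of 0.982 between the controls, 0.968 between the sesaminol libraries and 0.950 to 0.966 between the groups (genes are not independent replicates). Sesaminol replicate 2 differed from the other 3 libraries in its share of mitochondrial counts. Mitochondrial genes held 1.44% of its counts (95% Wilson interval 1.44 to 1.45), against 3.36% (3.35 to 3.37) in sesaminol replicate 1, 3.06% (3.05 to 3.07) in control replicate 1 and 2.95% (2.94 to 2.96) in control replicate 2. A count was recorded for 31253 genes in sesaminol replicate 2 and for 26531 to 27336 in the others. These numbers were not adjusted for depth, and sesaminol replicate 2 had the largest total. Intervals cover counting error only, and are too narrow if both reads of a pair were counted singly.

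The comparison asked how sesaminol altered gene expression, and that of muscle differentiation genes in particular. Genes of the contractile apparatus were lower in the sesaminol libraries. Actn2, which encodes the Z-disc protein alpha-actinin 2, stood at 103 ± 9.57 CPM (SD, n = 2) in controls and 8.86 ± 1.67 CPM with sesaminol, and Mb, which encodes the oxygen carrier myoglobin, at 498.5 ± 61.6 and 44.0 ± 10.9 CPM. In the lists of cholesterol synthesis, the NRF2 antioxidant response, and glycolysis and hypoxia, 16 of 25, 11 of 35 and 10 of 26 genes rose (camera adjusted p = 0.315, 0.195 and 0.231 with an estimated correlation). Also higher were the lipid droplet coat gene Plin2 (144 ± 15.7 and 771 ± 9.36 CPM) and the peptide hormone gene Apln (1.78 ± 1.69 and 31.9 ± 0.12 CPM). Of 18998 genes tested, 516 rose and 615 fell with sesaminol (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Changes of at least 2-fold made up 294 of the rises and 481 of the falls. Protein-coding genes accounted for 455 of the rises and 524 of the falls. The 2 groups did not overlap for 8937 genes, 47% of those tested, where chance alone gives 33.3% on average. Genes share differences between whole libraries, so the excess over 33.3% is not a test of sesaminol. Without control replicate 1 or 2 the test called 510 and 452 genes, and without sesaminol replicate 1 or 2 it called 4642 and 2939. In each of these fits the lone library was assumed to vary like the other group.

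The 10 largest rises among named genes with a mean of at least 5 CPM were in Apln, Rgs2, Slco4a1, Cd68, Kif1a, Fez1, Atp6v0d2, Ndrg1, Thbd and Grem1, from 19.1-fold for Apln to 7.37-fold for Grem1. Apln (ENSMUSG00000037010, chromosome X, 48025146 to 48034853, GRCm38) rose by 4.25 ± 0.48 (SE) on the log2 scale (edgeR adjusted p = 0.00189), and its fold rested on few control reads: it was 53.7 without control replicate 1 and 10.7 without control replicate 2. Rgs2, a regulator of G protein signalling, rose from 2.43 ± 0.905 to 36.0 ± 18.5 CPM (14.4-fold, edgeR adjusted p = 0.00163; 8.89-fold without sesaminol replicate 1). Kif1a and Fez1, a kinesin motor and a kinesin adaptor known from neurons, rose 8.83-fold and 8.17-fold. Thbd, encoding the anticoagulant receptor thrombomodulin, rose from 35.0 ± 7.16 to 262 ± 29.4 CPM, and Grem1, encoding a secreted antagonist of bone morphogenetic proteins, from 83.7 ± 16.4 to 617 ± 169 CPM. Atp6v0d2, a subunit of the vacuolar proton pump, rose from 2.48 ± 0.417 to 20.3 ± 8.83 CPM. The 10 largest falls included those of Chst13, Dhrs7c, R3hdml, Actn2, Mb, Nefl, Hnf4aos, Casq1 and Tceal7, from 15.5-fold to 9.58-fold. Chst13, a chondroitin sulfotransferase gene, fell from 9.66 ± 2.20 to 0.603 ± 0.0957 CPM, and Dhrs7c, a dehydrogenase gene of the sarcoplasmic reticulum, from 16.3 ± 0.590 to 1.24 ± 0.0440 CPM. Of these 20 genes, 4 were marked as sharing reads, and their values are uncertain for that reason. They were Ndrg1 with Gm17035 (66.5% of its count), Nefl with Nefm (32.1%), and R3hdml and Hnf4aos with each other. Slco4a1, a transporter gene, rose 11.2-fold, but 17.2-fold without control replicate 2 and 5.6-fold without sesaminol replicate 2, and was not called by limma-voom. Without sesaminol replicate 1 or 2 the fall of Nefl was 31.7-fold and 5.89-fold, and that of Tceal7 20.6-fold and 5.76-fold.

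Muscle genes fell as a group. Over the 4 muscle lists joined, 74 of 123 tested genes fell and 4 rose; adjusted over the list alone, 91 fell and 4 rose. The median log2 fold change was -1.13, and camera, a test of whether a list moves relative to the other genes, gave p = 2.28e-73, and p = 0.0184 with an estimated correlation. Of 45 sarcomere and contraction genes, 39 fell and the other 6 did not pass (44 fell adjusted over the list alone). Actn2 (ENSMUSG00000052374, chromosome 13, 12269426 to 12340760, GRCm38) fell by 3.55 ± 0.20 (SE) on the log2 scale (edgeR adjusted p = 0.000319). Myh8, the perinatal myosin heavy chain gene, fell from 146.5 ± 17.6 to 16.9 ± 0.410 CPM (8.67-fold, edgeR adjusted p = 0.000319), and Tcap, encoding the titin cap protein, 8.58-fold. Myh3, the embryonic myosin heavy chain gene, fell 2.93-fold from 2544 ± 301 CPM. Acta1, skeletal muscle actin, was 2.12-fold lower and missed the threshold (edgeR adjusted p = 0.0709). Of 32 genes of excitation-contraction coupling and muscle energy, 19 fell and the other 13 did not pass (25 fell adjusted over the list alone), among them Casq1, the calcium store protein calsequestrin (67.0 ± 2.18 to 7.07 ± 3.25 CPM), Scn4a, the muscle sodium channel (4.50-fold), and Ckm, muscle creatine kinase (482 ± 13.8 to 134 ± 96.5 CPM, 3.61-fold, edgeR adjusted p = 0.0373), which shares reads with A930016O22Rik and was not called by DESeq2. The fall of Ckm was 7.53-fold without sesaminol replicate 1 and 2.37-fold without sesaminol replicate 2.

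Among 23 myogenic regulators, 11 fell and 2 rose (12 and 2 adjusted over the list alone). Mef2c, a transcription factor that activates muscle genes, fell 7.98-fold, from 99.9 ± 19.6 to 12.5 ± 0.625 CPM (edgeR adjusted p = 0.00041). Klhl41 and Lmod3, which act in myofibril and thin filament assembly, fell 3.40-fold and 3.22-fold. The myogenic factors Myod1 and Myog fell by 1.02 ± 0.22 and 1.20 ± 0.27 (SE) on the log2 scale (edgeR adjusted p = 0.0307 and 0.033), while Myf5 had a log2 fold change of 0.22 ± 0.27 (edgeR adjusted p = 0.783). The transcriptional cofactors Eya1 and Eya4, named after their values were seen, rose 2.63-fold and 2.13-fold. Of 23 genes of myoblast fusion and adhesion, 5 fell and 2 rose (10 and 2 adjusted over the list alone). Adam12, a metalloprotease of fusing myoblasts, fell 4.65-fold, Cav3, muscle caveolin, 2.79-fold and Tmem182, a muscle membrane protein gene, 2.27-fold, and Neo1, the netrin receptor neogenin, rose 2.27-fold. Dysf and Itga7 fell 1.92-fold and 1.98-fold and Cd9 rose 1.84-fold, and these 3 were named after their values were seen. Camera found all 4 muscle lists lower (adjusted p = 1.07e-81 for sarcomere, 6.14e-34 for coupling and energy, 4.23e-11 for regulators and 2.04e-05 for fusion). With an estimated correlation the adjusted p was 0.195 for the first 3 and 0.274 for fusion. With control replicate 1 or 2 left out, 48 and 44 of the muscle genes fell and 1 and 2 rose, and the falls numbered 25 and 23 for sarcomere, 7 and 6 for regulators, 12 and 13 for coupling and energy and 4 and 2 for fusion. With sesaminol replicate 1 or 2 left out, 13 and 11 fusion genes fell. Without control replicate 1, 1 regulator rose, and without either control 0 fusion genes rose. Myod1, Myog and Myh3 each missed the threshold without either control, with edgeR adjusted p from 0.101 to 0.381, as did Neo1 (0.147 and 0.0507), and Tmem182 missed it without control replicate 2 (0.0788).

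**Figure D1:**
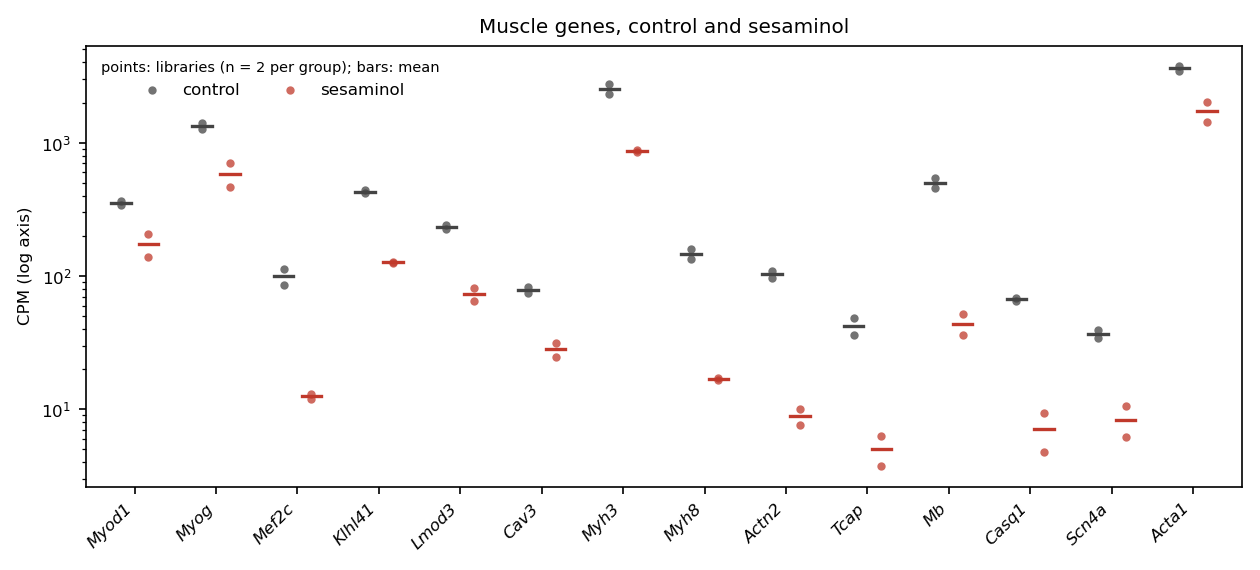
CPM (log axis) of 14 muscle genes in the 2 control and 2 sesaminol libraries, with a point per library and a bar at each group mean. Both sesaminol libraries lie below both control libraries for each gene, from Mb, with means of 498.5 and 44.0 CPM, to Acta1, with means of 3626 and 1713 CPM, which missed the test's threshold.

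Genes of cholesterol synthesis rose, and so did some genes of fat synthesis and storage. Of 25 cholesterol synthesis genes, 16 rose and the other 9 did not pass (22 rose adjusted over the list alone), with a median log2 fold change of 1.07 (camera adjusted p = 3.74e-22, and adjusted p = 0.315 with an estimated correlation). Sqle, squalene epoxidase, rose from 201 ± 15.3 to 516 ± 109 CPM (edgeR adjusted p = 0.00768), Sc5d, a late sterol desaturase, 2.41-fold, and Stard4, a sterol carrier gene, 2.43-fold. Of 28 adipocyte and lipid droplet genes, 5 rose and 2 fell (9 and 3 adjusted over the list alone; camera adjusted p = 0.00592, and adjusted p = 0.408 with an estimated correlation). Those that rose were Plin2 (ENSMUSG00000028494, chromosome 4, 86648386 to 86670060, GRCm38), up by 2.42 ± 0.21 (SE) on the log2 scale (edgeR adjusted p = 0.000766), Lpin1, a phosphatidate phosphatase gene (2.90-fold), Fasn, fatty acid synthase (287 ± 6.74 to 894 ± 270 CPM), Acaca, acetyl-CoA carboxylase (1.71-fold), and Plin4, 4.94-fold higher with reads shared with Hdgfl2. Slc2a4, the insulin-responsive glucose transporter gene, fell 16.7-fold (27.7-fold without sesaminol replicate 2). It stood at 3.965 ± 0.692 CPM in controls and 0.216 ± 0.116 CPM with sesaminol. The latter is near the 3-count limits of 0.201 and 0.112 CPM in sesaminol replicates 1 and 2, so the size of this fold is uncertain. Cd36, a fatty acid uptake gene, fell 2.42-fold. Slc2a4, Cd36 and Acaca were named after their values were seen. The adipocyte regulators Pparg and Cebpa had log2 fold changes of 0.38 ± 0.24 and 0.79 ± 0.21 and did not pass the test (edgeR adjusted p = 0.491 and 0.0652), nor did the fatty acid binding protein gene Fabp4 (2.64 ± 1.05 and 1.23 ± 0.156 CPM; edgeR adjusted p = 0.357). Adipoq had 6 to 12 counts per library and was not tested. Ucp1 had 0 counts in both controls, which allows up to 0.298 and 0.219 CPM, and 2 and 10 counts with sesaminol, and was not tested. Those limits are higher if both reads of a pair were counted singly. With control 1, control 2, sesaminol 1 and sesaminol 2 left out in turn, 8, 4, 18 and 23 cholesterol genes rose, 3, 3, 7 and 10 adipocyte genes rose and 1, 0, 6 and 6 adipocyte genes fell. Without sesaminol replicate 1, 1 cholesterol gene fell. The adipocyte list missed the threshold without control replicate 1 or sesaminol replicate 1 (camera adjusted p = 0.107 and 0.0956) and when genes with shared reads were left out (0.0854). Sqle and Fasn missed it without either control (edgeR adjusted p from 0.0865 to 0.182), and Stard4 without control replicate 2 (0.0805).

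The lists of brown fat and fatty acid oxidation genes did not pass as groups. Of 16 brown and beige fat genes, 1 rose and 2 fell (1 and 3 adjusted over the list alone; camera adjusted p = 0.327). The elongase gene Elovl6 rose 4.60-fold, from 38.9 ± 1.61 to 179 ± 104 CPM (2.64-fold without sesaminol replicate 1), Fgf21, a metabolic hormone gene, fell 4.16-fold, and Dio2, the thyroid hormone deiodinase gene, fell 1.97-fold. Ppargc1a, a coactivator of mitochondrial genes, had a log2 fold change of 0.85 ± 0.35 (edgeR adjusted p = 0.238). Of 24 fatty acid oxidation genes, the other 22 did not pass while Cpt1a, which brings fatty acids into mitochondria, and Angptl4, an inhibitor of lipoprotein lipase, rose (1.84-fold and 2.27-fold; also 2 adjusted over the list alone). That list had a median log2 fold change of -0.09, but its mean of 0.01 and camera's direction were upward (adjusted p = 0.936). The brown fat list had 1, 1, 4 and 2 genes higher and 2, 1, 4 and 4 lower with control 1, control 2, sesaminol 1 and sesaminol 2 left out in turn, and fatty acid oxidation had 0, 0, 2 and 3 higher and 6 lower without sesaminol replicate 1. Cpt1a and Angptl4 missed the threshold without either control (edgeR adjusted p from 0.0629 to 0.217), and Dio2 missed it without control replicate 2 (0.243), with upper quartile scaling or library size alone and with a gene length correction.

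Genes of the response to oxidants and electrophiles rose. Of 35 NRF2 and glutathione genes, 11 rose and the other 24 did not pass (18 rose adjusted over the list alone; camera adjusted p = 2.58e-15, and adjusted p = 0.195 with an estimated correlation). Nqo1 (ENSMUSG00000003849, chromosome 8, 107388225 to 107403206, GRCm38), a quinone reductase, rose from 5.75 ± 0.546 to 30.1 ± 5.25 CPM, by 2.38 ± 0.23 (SE) on the log2 scale (edgeR adjusted p = 0.00114). The glutathione transferases Gsta4 and Gstm1 rose 3.59-fold and 3.07-fold, the epoxide hydrolase Ephx1 3.11-fold, and the heme oxygenase Hmox1 1.80-fold (edgeR adjusted p = 0.0153, and 0.264 and 0.233 without control replicate 1 or 2). Among 17 aryl hydrocarbon receptor and xenobiotic genes, 2 rose and 1 fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.28). The 2 that rose, Ugt1a6a and Ugt1a7c, share exons and reads, and the one that fell was the estrogen receptor gene Esr1 (2.43-fold). Cyp1a1 stood at 0.955 ± 0.508 and 4.25 ± 0.425 CPM (edgeR adjusted p = 0.0509), and Cyp1b1 had a log2 fold change of -0.41 ± 0.23 (edgeR adjusted p = 0.42). Of 26 glycolysis and hypoxia genes, 10 rose and the other 16 did not pass (14 rose adjusted over the list alone; camera adjusted p = 2.22e-15, and adjusted p = 0.231 with an estimated correlation). They included Mxi1, an antagonist of Myc (2.73-fold), and, with shared reads, the glucose transporter Slc2a1 (3.68-fold), Ndrg1 (8.03-fold) and Bnip3 (2.50-fold). Leaving out control replicate 1 or 2 left 5 and 5 genes that rose in each of the NRF2 and glycolysis lists, and leaving out sesaminol replicate 2 gave 22 and 20. The NRF2 count was 17 without sesaminol replicate 1, where 1 gene of each list fell. In the xenobiotic list 4 rose without sesaminol replicate 2, and 2 fell without sesaminol replicate 1 or 2. Esr1 missed the threshold without control replicate 2 (edgeR adjusted p = 0.151), with upper quartile scaling or library size alone and with counts thinned to the smallest library total.

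Of 27 muscle atrophy and autophagy genes, 6 rose and the other 21 did not pass (9 rose and 1 fell adjusted over the list alone; camera adjusted p = 2.37e-05, and adjusted p = 0.195 with an estimated correlation). The leading member was the metallothionein gene Mt1 (61.1 ± 10.5 to 290 ± 55.2 CPM, edgeR adjusted p = 0.00114), followed by the mitophagy receptors Bnip3 and Bnip3l (2.50-fold and 1.78-fold) and the autophagy kinase Ulk1 (1.77-fold). Of 22 inflammation and NF-kB genes, 4 rose and 1 fell (6 and 4 adjusted over the list alone; camera adjusted p = 0.0243, and adjusted p = 0.274 with an estimated correlation). Those that rose were Mt1 and, with shared reads, Mt2 (6.22-fold), which encode metal-binding proteins, Ptgs2, cyclooxygenase 2 (3.22-fold), and the chemokine gene Ccl7 (2.30-fold, named after its value was seen), while the cytokine gene Lif fell 3.22-fold. Of 19 interferon response genes, 3 rose and the other 16 did not pass (7 rose adjusted over the list alone; camera adjusted p = 0.00622, and adjusted p = 0.26 with an estimated correlation): Ifit3 (3.77-fold), Ifit2 (2.27-fold) and Stat2 (1.85-fold). Of 19 macrophage and leukocyte markers measured, only 6 had enough counts to be tested. Among these 6, Cd68 and Cd14 rose (also 2 adjusted over the list alone, with camera adjusted p = 0.00661, and adjusted p = 0.408 with an estimated correlation). Cd68 rose from 1.18 ± 0.0164 to 10.5 ± 2.10 CPM and Cd14 from 9.33 ± 1.42 to 28.3 ± 4.09 CPM. The atrophy list had 2, 2, 8 and 12 genes higher with control 1, control 2, sesaminol 1 and sesaminol 2 left out in turn and 0, 0, 2 and 2 lower, the interferon list 1, 1, 7 and 6 higher, and the inflammation list 3, 3, 5 and 8 higher, with 0, 1, 6 and 4 lower. The inflammation list missed the threshold without control replicate 1 or sesaminol replicate 1 (camera adjusted p = 0.0771 and 0.0914) and when genes with shared reads were left out (0.332), and the marker list without sesaminol replicate 2 (0.0704) or with no filter on low counts (0.158). Bnip3l, Ulk1 and Stat2 missed it without either control (edgeR adjusted p from 0.115 to 0.435), as did Lif and Ifit2 without control replicate 1 (0.0601 and 0.147) and Ifit3 without control replicate 2 (0.0507).

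Extracellular matrix genes fell. Of 36 matrix and fibroblast genes, 12 fell and 1 rose (15 and 1 adjusted over the list alone; camera adjusted p = 3.99e-09, and adjusted p = 0.26 with an estimated correlation). Col1a1, a chain of collagen I, fell from 860 ± 47.9 to 371 ± 14.4 CPM (edgeR adjusted p = 0.0104), Thbs2, thrombospondin 2, 2.29-fold, and Tnc, tenascin C, 3.98-fold with reads shared with an overlapping transcript. Of 21 smooth muscle and TGF-beta genes, 4 fell and 1 rose (8 and 1 adjusted over the list alone; camera adjusted p = 3.68e-05, and adjusted p = 0.195 with an estimated correlation). The falls were in the smooth muscle actins Actg2 (3.94-fold) and Acta2 (2.00-fold, named after its value was seen), and, with shared reads, in Tagln, transgelin (5.16-fold), and Tgfb3 (2.26-fold), while the receptor Tgfbr1 rose 1.87-fold. Of 18 Notch and reserve cell genes, 4 fell and 2 rose (8 and 3 adjusted over the list alone; camera adjusted p = 0.0216, and adjusted p = 0.274 with an estimated correlation). The Notch effector genes Heyl and Hes1 fell 7.58-fold and 2.51-fold, from 46.6 ± 4.09 to 6.36 ± 4.46 CPM and from 66.2 ± 4.15 to 26.5 ± 10.8 CPM. Without sesaminol replicate 1 or 2 the fall of Heyl was 14.9-fold and 4.86-fold. With shared reads, the receptors Notch3 and Notch1 fell 2.33-fold and 2.07-fold and Cd34, a surface marker of reserve cells, rose 3.31-fold. Sdc4, a syndecan gene, rose 1.80-fold; it and Notch1 were named after their values were seen. With control 1, control 2, sesaminol 1 and sesaminol 2 left out in turn, 3, 2, 23 and 18 matrix genes, 2, 2, 10 and 9 smooth muscle genes and 4, 2, 10 and 7 Notch genes fell, and 0, 0, 4 and 5 matrix genes, 0, 0, 1 and 2 smooth muscle genes and 1, 1, 3 and 3 Notch genes rose. Col1a1 missed the threshold without either control (edgeR adjusted p = 0.123 and 0.217), as did Tgfbr1 (0.279 and 0.0978), Thbs2, Tgfb3 and Notch3 missed it without control replicate 2 (0.0577, 0.0518 and 0.0947) and Actg2 without control replicate 1 (0.226). The Notch list missed it when genes with shared reads were left out (camera adjusted p = 0.0854).

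In the cell cycle list, 3 of 38 genes fell and the other 35 did not pass (4 fell adjusted over the list alone; camera adjusted p = 0.00102, and adjusted p = 0.711 with an estimated correlation). E2f2, a transcription factor of the G1 to S transition, fell 2.65-fold (edgeR adjusted p = 0.00295). Ube2c and Ccnd3 were 2.80-fold and 2.08-fold lower. Both were marked as sharing reads, with the troponin gene Tnnc2 at 97.4% of Ube2c's count and Bysl at 29% of Ccnd3's. Mki67, a proliferation marker, stood at 23.9 ± 4.01 and 15.5 ± 14.2 CPM (edgeR adjusted p = 0.635). The list rested on sesaminol replicate 2: without it the direction turned upward (camera adjusted p = 0.825), with 3 members higher and 4 lower past the threshold, and without sesaminol replicate 1, 27 members fell and 1 rose. Ccnd3 missed the threshold without control replicate 1 or 2 (edgeR adjusted p = 0.271 and 0.303). None of 14 mitochondrially encoded transcripts passed in edgeR (also 0 adjusted over the list alone, 2 at an unadjusted p under 0.05, 0 with DESeq2 and 0 with limma-voom; camera adjusted p = 0.21). That list moved with the same library: 11 members fell without sesaminol replicate 1 (camera adjusted p = 7.44e-12), and without sesaminol replicate 2 the list was higher (0.0395), with 3 members up.

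The other lists did not pass camera's threshold. Of 23 p53 targets, 3 rose and 2 fell (4 and 2 adjusted over the list alone; camera adjusted p = 0.327): Trp53inp1, Zmat3 and, with shared reads, Ei24 rose (2.48-fold, 2.02-fold and 1.89-fold), and Pmaip1 and Ddit4l fell (1.78-fold and 1.85-fold), Ddit4l having been named after its value was seen. Cdkn1a, the p21 gene, had a log2 fold change of -0.40 ± 0.25 (edgeR adjusted p = 0.491). Bmp4, a bone morphogenetic protein gene, rose 1.95-fold among 13 osteoblast and chondrocyte genes (3 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.281), and Fzd4, a Wnt receptor gene, 2.11-fold among 27 Wnt targets (also 1 adjusted over the list alone; camera adjusted p = 0.779). With control 1, control 2, sesaminol 1 and sesaminol 2 left out in turn, 0, 1, 5 and 6 p53 targets rose and 0, 0, 3 and 5 fell, 0, 0, 2 and 7 osteoblast genes rose (camera adjusted p = 0.0195 in the last), and 0, 1, 5 and 2 Wnt targets rose, while 0, 0, 2 and 1 osteoblast genes and 0, 0, 1 and 2 Wnt targets fell. Zmat3, Ei24, Pmaip1 and Bmp4 missed the threshold without either control (edgeR adjusted p from 0.0672 to 0.413), and Trp53inp1 and Fzd4 without control replicate 1 (0.063 and 0.265). Pmaip1 also missed it with a GC content correction.

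No gene passed in edgeR in 5 further lists, nor when adjusted over the list alone. For 30 unfolded protein and ATF4 genes (camera adjusted p = 0.335), 9 had an unadjusted p under 0.05, and DESeq2 called 1 higher and 1 lower and limma-voom 0. Ddit3, a stress transcription factor gene that shares reads with Mars, had a log2 fold change of 0.59 ± 0.24 (edgeR adjusted p = 0.247). For 34 oxidative phosphorylation genes (camera adjusted p = 0.0589) the unadjusted count was 3, with 1 lower in DESeq2 and 0 in limma-voom. For 12 endothelial and nerve markers (camera adjusted p = 0.327) it was 1, with 0 in DESeq2 and 1 lower in limma-voom. Of 22 replication-dependent histones measured in these poly(A)-selected libraries, only 8 had enough counts to be tested. For these 8 (camera adjusted p = 0.645, upward, with a median log2 fold change of 0.17 and a mean of -0.01) the unadjusted count was 1. For 39 ribosomal protein genes (camera adjusted p = 0.783) it was 4, with 0 in DESeq2 and limma-voom for both lists. The unfolded protein list passed camera without control replicate 1 or sesaminol replicate 1 (adjusted p = 0.0334 and 0.000192), where 0 and 14 members fell and 0 and 2 rose. Without sesaminol replicate 2 its direction turned upward (0.391), with 6 members higher and 1 lower. Oxidative phosphorylation passed without control replicate 2 or sesaminol replicate 1 (0.0157 and 0.0483), where 1 and 10 members fell and 0 and 2 rose, and with upper quartile scaling (0.0301) or no filter on low counts (0.0241). The endothelial and nerve list passed without control replicate 2 (0.0164), and 1, 1, 2 and 2 of its members fell with control 1, control 2, sesaminol 1 and sesaminol 2 left out in turn. Without sesaminol replicate 1, 5 ribosomal protein genes rose and 5 fell, and without sesaminol replicate 2, 1 histone rose and 1 oxidative phosphorylation gene fell.

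**Figure D2:**
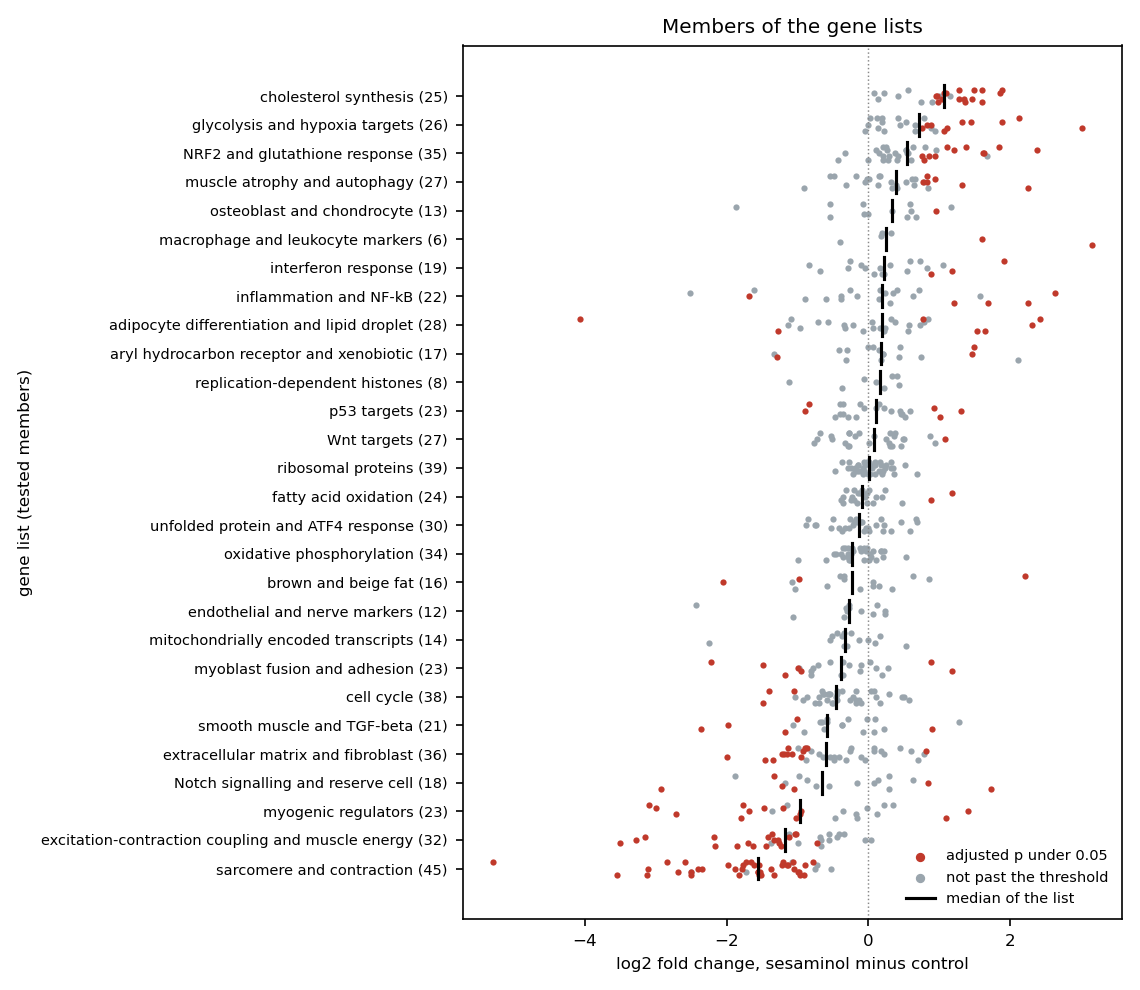
Log2 fold change (sesaminol minus control) of each tested member of the 28 gene lists, with members past the adjusted p threshold in red, others in grey and a black bar at each list's median. Medians run from 1.07 for cholesterol synthesis to -1.55 for sarcomere and contraction, where 39 of 45 members are red.

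**Figure D3:**
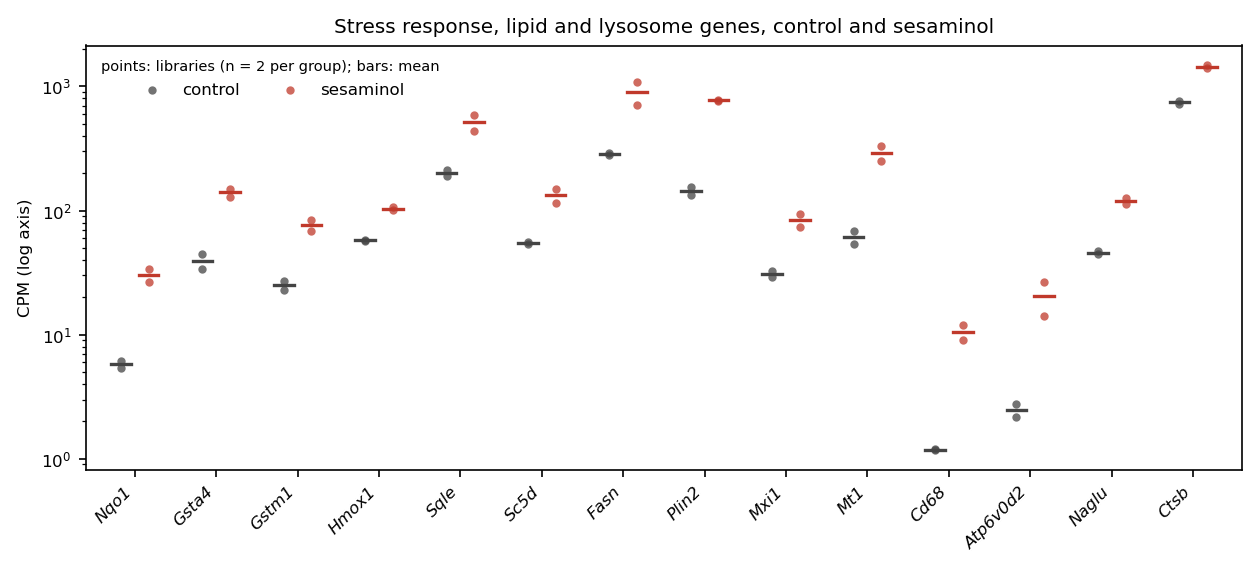
CPM (log axis) of 14 stress response, lipid and lysosome genes (Naglu and Ctsb chosen after the data were seen) in the 2 control and 2 sesaminol libraries, with a point per library and a bar at each group mean. Both sesaminol libraries lie above both control libraries for each gene, for example Nqo1 with means of 5.75 and 30.1 CPM and Plin2 with means of 144 and 771 CPM.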

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

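The tests on thinned or halved counts, on GC content, on gene length and without overlapping genes were chosen after the data were seen. None of the genes called in the full comparison changed sign in any fit where it was tested. This was largely fixed in advance, as the groups did not overlap for any of the 1131 called genes. The smallest change among them was 0.639 on the log2 scale. It therefore says little about how firm the calls are. With DESeq2's size factors 1068 genes changed (466 higher, 602 lower), with upper quartile scaling 1094 (436 higher, 658 lower) and with library size only 1095 (552 higher, 543 lower, so that rises outnumbered falls), with DESeq2 1441 and with limma-voom 1034, and muscle genes called lower numbered 71 to 88 across scalings, filters and tools. With no filter on low counts 1913 genes changed (928 higher, 985 lower). At an adjusted p under 0.01, 428 changed (164 higher, 264 lower). At an adjusted p under 0.05 with a change of at least 2-fold, 775 changed (294 higher, 481 lower). The libraries share only the numbers 1 and 2: deviations of same-numbered libraries correlated at -0.0536, and with the replicate number as a block 1875 genes changed (893 higher, 982 lower) and the mitochondrial list passed (camera adjusted p = 0.0479). Leaving out 1 library gave 452 to 4642 changed genes, 163 to 1918 higher and 276 to 2724 lower, and among muscle genes 44 to 98 lower and 1 to 5 higher. By construction, without a control the spread came from the sesaminol pair alone, and without a sesaminol library from the control pair alone. Of 92 named genes with a call, 25 missed the threshold without control replicate 1 and 28 without control replicate 2. Among the other settings, Dio2 and Esr1 missed it with upper quartile scaling and with library size only, Ckm with DESeq2, Slco4a1 with limma-voom, Esr1 with thinned counts, Pmaip1 with the GC correction and Dio2 with the gene length correction.

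Of 16 lists that passed camera, 0 passed with an estimated correlation and 7 with the directional fry test; fry's mixed test passed 20 lists. Directions of lists turned as follows, each with camera's adjusted p, and apart from cell cycle none of these lists had passed. Fatty acid oxidation turned with upper quartile scaling (0.981) and the GC correction (0.998), histones with no filter (0.966) and the xenobiotic list without overlapping genes (0.874). With 1 library left out, some fits turned direction, and the lowest and highest adjusted p over the 4 fits were 0.202 and 0.814 for fatty acid oxidation, 0.2003 and 0.891 for Wnt targets, 0.352 and 0.942 for ribosomal proteins, 0.000192 and 0.804 for the unfolded protein list, 1.36e-14 and 0.825 for cell cycle and 7.44e-12 and 0.0771 for mitochondrial transcripts. Among these, cell cycle turned upward at 0.825 and mitochondrial transcripts at 0.0395, both without sesaminol replicate 2. Log2 fold changes of uncalled genes that turned ran from -0.12 to 0.48 for Vwf, -1.14 to 0.27 for Hist1h1e, -1.435 to 0.11 for Itgam, -0.36 to 0.63 for Myf5, -1.15 to 0.26 for Gap43, -1.51 to 0.026 for mt-Nd1 and -2.18 to 0.10 for Mki67. The causes were not tested. In the simulation at this depth and with 2 libraries per group, 32 of 100 genes changed 2-fold were recovered.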

Other observations

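The gene lists in this part were set after the data had been seen. The tests of how reads were assigned and counted and of spanning genes were chosen only after their own result was seen. So were those of an equal fall of every sarcomere transcript and of leukocyte transcripts. The others were chosen after the data were seen but before their own result was. Of 37 lysosome genes, 19 rose and the others did not pass, with a median log2 fold change of 0.74 (camera adjusted p = 8.19e-23 over 4 lists, and adjusted p = 0.0292 with an estimated correlation). As some genes of the list had been seen to rise before it was set, a rise of the group is a hypothesis only; for the 36 genes left without Atp6v0d2, already reported, 18 of which rose, camera's adjusted p was 3.77e-21, and 0.0371 with an estimated correlation. They included the sugar-cleaving hydrolases Naglu (45.6 ± 1.85 to 120 ± 9.14 CPM, SD, n = 2, edgeR adjusted p = 0.00215) and Gla (12.1 ± 0.840 to 40.9 ± 9.49 CPM). Also among them were the proton pump subunit Atp6v1a (145 ± 8.92 to 358 ± 27.3 CPM), the cholesterol-binding protein Npc2 (log2 fold change 1.07 ± 0.20, SE) and the protease Ctsb (746 ± 30.0 to 1445 ± 69.5 CPM). Without control replicate 1 or 2, 4 and 5 lysosome genes rose, and without sesaminol replicate 1 or 2, 27 and 29 rose and 1 and 1 fell, with camera's adjusted p at most 3.92e-16 in these 4 fits.

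Of 18 fatty acid synthesis genes, 7 rose (5 of the 19 genes listed stood also in a list fixed earlier; camera adjusted p = 4.6e-07, and adjusted p = 0.322 with an estimated correlation; over the 13 genes not reported before and in no fixed list 6.4e-05 and 0.318). Acly, which makes cytosolic acetyl-CoA, rose from 136 ± 8.36 to 291 ± 101 CPM. Srebf1, which shares reads with Rai1, had a log2 fold change of -0.35 ± 0.21 (SE, edgeR adjusted p = 0.462). Of 28 SRF and YAP target genes, 7 fell and 1 rose (6 of the 29 genes listed stood also in a list fixed earlier; camera adjusted p = 1.07e-06, and adjusted p = 0.0617 with an estimated correlation; over the 23 genes not reported before and in no fixed list 0.00448 and 0.217), with Ankrd1 at 972 ± 146 and 449 ± 86.4 CPM and Myl9 at 29.0 ± 1.72 and 9.41 ± 0.133 CPM. Among 21 heat shock genes 2 rose and 1 fell, and the group did not pass (camera adjusted p = 0.0665, and adjusted p = 0.351 with an estimated correlation), nor did it with any 1 library left out (0.0542 to 0.619), where 1, 1, 4 and 4 rose and 1, 1, 3 and 1 fell without control 1, control 2, sesaminol 1 and sesaminol 2. Without control replicate 1 or 2, 2 and 1 fatty acid synthesis genes rose and 2 and 4 SRF and YAP target genes fell, and without sesaminol replicate 1 or 2, 7 and 13 of the former rose and 15 and 13 of the latter fell. In the same order, 0, 0, 2 and 0 fatty acid synthesis genes fell and 0, 1, 3 and 3 SRF and YAP target genes rose.

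The lower muscle genes were set against technical explanations. Of the 74 muscle genes that fell, 73 were still lower after all libraries were thinned to the smallest total. After a GC correction 71 were still lower, and after the gene length correction, which used genomic span, 68 were. This argues against depth, GC content and genomic span as the whole cause. Transcript length was not tested. Among the 97 tested muscle genes not marked as sharing reads, 60.8% fell, and among the 93 for which no overlapping gene of any kind, spanning genes included, held 20% of their count, 62.4% fell, which argues against shared reads as the whole cause. One equal fall of every sarcomere transcript is argued against: of the 45 tested genes of the list fixed in advance, 21 (46.7%, against under 10% for an equal fall, a bound set after the fold changes were seen) lay over 2 SE from their weighted mean log2 fold change of -1.53 (Cochran's Q, computed before that share, was 431), with Actn2 at -3.55 ± 0.20 and Tnni2 at -1.06 ± 0.19 (SE). Tnni2 was named after its value was seen. Whether fewer myotubes or less mature ones caused the uneven fall stays open: 10 of 17 early myotube genes and 22 of 25 mature fibre genes fell, with medians of -1.14 and -2.18 (two-sided permutation p = 0.00435, 100000 permutations), but both sets were picked after their fold changes were seen, so this p decides nothing.

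Many overlapping genes had counts that pointed to shared reads. Over 24 genes that span 200000 bp or more and hold others, the median ratio of the gene's count to the summed count of the genes inside was 1.03, with a range of 0.412 to 2.75 and 15 of the 24 near 1, within the bounds set for this test, which is consistent for most of them with reads counted over whole gene bodies, on either strand and into every overlapping gene. The lowest share of even values from 1 to 12 in a library was 75.8%, which is consistent with both reads of a pair counted singly. Mt2 and Gm45774, which overlap on chromosome 8 (94172664 to 94173568 and 94170748 to 94173412, GRCm38), had 2976 and 2898 counts in sesaminol replicate 1, and Ube2c and Tnnc2 had 3669 and 3365. Shared reads did not make most of the calls, since 29.9% of the 1128 called genes with a known position were marked as sharing reads. Among the 18952 tested genes with a known position, 36.9% were marked. With spanning genes counted in full these shares were 31.6% and 38.4%. Of the 72 antisense genes called, 67 were marked. The share among all 1212 antisense genes tested was not computed, so this does not show that shared reads made those calls.

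Cd68 and Cd14, known from macrophages, rose in a line of myoblasts. The summed level of 16 abundant macrophage transcripts was 2.11 times that of Cd68 in the sesaminol libraries, which met the bound set for leukocytes, but 15.5 of the 22.2 CPM were Csf1r, which shares reads with Hmgxb3, and the controls already held 21.1 CPM. Over the 10 transcripts without such an overlapping gene, a test added after that value was seen, the ratio was 0.263. C1qa and Laptm5 had no counts in the sesaminol libraries, nor in the controls. For these 10 transcripts this argues against leukocytes. The ratios disagree, however, and Csf1r was left out only by a mark that does not show shared reads. Of the 7 of the 16 that were tested, 0 passed edgeR's test (1 at an unadjusted p under 0.05, lower), and Lyz2 stood at 0.171 CPM. Cd68 is also a lysosomal membrane protein, and its rise may belong with that of the lysosome genes, which was not tested.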
